A study of Rattus norvegicus with 4 samples.

How the data were processed

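Peripheral blood mononuclear cells (PBMC) of pregnant rats were profiled by droplet single-cell RNA sequencing on the 10x Chromium platform, in 2 oil-treated control samples and 2 samples treated with 2,3,7,8-tetrachlorodibenzo-p-dioxin (TCDD), a ligand of the aryl hydrocarbon receptor (AHR). TCDD was given at gestational day 6.5 and blood cells were collected at gestational day 13.5. The labels number the samples within each group and do not say whether they came from separate animals or from pools, so the p-values measure the spread between these samples, which may be partly technical.

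The deposited matrices hold UMI counts per gene and barcode, not normalized, made with Cell Ranger 4.0.0 per the file headers. The genome build was rn6 per the submitters' processing notes. The annotation version and the settings of the cell calling are not given in the sources used here, and no coordinates were used. Gene symbols and Ensembl identifiers were taken from the deposited feature lists, which name 25199 genes in each library. Genes with near-identical copies, such as the alpha and beta globins, share reads, and their separate counts are uncertain. The same holds for large receptor families.

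Barcodes with at least 500 UMIs, at least 200 detected genes and at most 10% of UMIs on mitochondrially encoded genes were kept. Of the 45197 barcodes, 2425 had too few genes and 12964 exceeded the mitochondrial limit, and no barcode lay under the UMI minimum. Doublets were scored per sample with the scrublet implementation in scanpy 1.11.5 at an expected rate of 8%. Its automatic threshold marked 2.73% and 0.022% of passing barcodes in oil replicates 1 and 2, and 0.070% and 4.70% in TCDD replicates 1 and 2. Because it failed under a rule fixed in advance, the 8% of barcodes with the highest scores were removed in every sample, 2548 in all, which left 29298 cells.

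The 4 samples were clustered together without batch integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with the sample as batch key, and 30 principal components, 15 neighbours and Leiden resolution 1.0 were used (Python 3.11.15, igraph 0.11.9). Clusters were named from marker genes fixed before the data were examined. The scoring rule was set after the clusters were seen. It compared the markers over clusters, with a minimum score of 0.6, a margin of 0.2 over the next class, at least 3 informative markers and at least 50 cells. Clusters 8 and 15 scored within that margin for 2 classes and cluster 17 was too small. Cluster 18 was led by Rag1, Dntt and Ptcra, genes of immature T cells, and was also left unnamed. The unnamed clusters held 2.59% and 9.02% of kept cells in oil replicates 1 and 2, and 1.53% and 0.520% in TCDD replicates 1 and 2. At this resolution no class of dendritic, basophil, eosinophil or platelet cells could be named. At resolution 2.0 a plasmacytoid dendritic-like class of 41, 14, 18 and 104 cells was named in oil replicates 1 and 2 and TCDD replicates 1 and 2, too few for a gene test.

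For each class with at least 20 cells in every sample, UMI counts were summed per sample and compared between TCDD and oil with edgeR 4.0.16 (R 4.3.3), using TMM factors, filterByExpr with a minimum count of 10, a robust quasi-likelihood fit and its F test. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Adjusted p-values named without a tool are from this test. Counts of genes at an unadjusted p under 0.05 are also given, and a share of about 0.05 of the genes tested would fall there without any difference. Levels per library and class are CPM values of the summed counts, scaled to the TMM-adjusted total of the tested genes. Levels of a cluster over all libraries are scaled to its plain total. Fold changes are log2 of TCDD over oil. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. The summed counts per library ranged from 29.8 to 33.7 M UMIs in all cells, 7.75 to 24.4 in T-like, 2.14 to 3.37 in B-like, 0.353 to 4.30 in NK-like and 1.89 to 15.4 in monocyte-like cells. Neutrophil-like and erythroid-like cells were too few in some samples and were not tested for genes. Differences between classes were tested as an interaction of class and treatment with the sample as a block. Shares of cells were compared with a two-sided exact permutation test, which cannot give a p below 0.333 with 2 samples per group. Intervals on shares are exact 95% binomial intervals, and these and all count intervals cover counting error only.

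The 24 gene lists were fixed in advance and tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over 113 tests. The calls were repeated with an estimated correlation and with fry. A list needed at least 3 tested genes.

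Genes are named by a rule fixed in advance. It takes up to 10 genes per direction past the threshold with a mean of at least 10 CPM, groups that do not overlap and a gene symbol. Where fewer than 5 passed, the 5 with the smallest p per direction are named as such. Cyp1a1, Cyp1b1, Ahrr, Tiparp, Nqo1 and Ahr are named wherever tested, and the members of passing lists with the smallest p are given. RGD1562667 and AABR07003235.1, which have no gene symbol, were named after their values were seen. The identifiers in the deposited feature lists are ENSRNOG00000019687 for Art2b, ENSRNOG00000000034 for Nuak2, ENSRNOG00000001807 for Sspn, ENSRNOG00000058105 for Hbb, ENSRNOG00000046216 for Cd300c2, ENSRNOG00000002802 for Cxcl1, ENSRNOG00000012181 for Lpl, ENSRNOG00000006767 for Cst7, ENSRNOG00000045888 for RGD1562667 and ENSRNOG00000022640 for AABR07003235.1.

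The pipeline was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes had a mean of at least 10 CPM and genes varied independently. The shares called therefore do not cover genes under 10 CPM, nor libraries in which many genes shift together. They are not the power of the tests on the real libraries. At 2-fold the pipeline called 0% of the changed genes in all cells, 87% in T-like, 68% in B-like, 18% in NK-like and 88% in monocyte-like cells. At 4-fold the shares were 31%, 100%, 98%, 90% and 100%. In the same order, 5, 14, 11, 9 and 18 unchanged genes were also called. Counts of the 2 libraries within a group differed by far more than sampling noise, with a chi-square per degree of freedom of 146.8 for oil and 248.0 for TCDD. For pairs of an oil and a TCDD library it ranged from 48.85 to 480.1, so no library was a copy of another.

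The alternatives chosen before the data were examined were DESeq2 1.42.0, RLE factors, library totals alone, no low-count filter, a replicate block, leaving out each sample, keeping doublets, a stricter cell filter of 1000 UMIs and 5% mitochondrial UMIs, Leiden resolutions of 0.5 and 2.0, named classes only, and edgeR on cell numbers. Added after seeing the data were a mitochondrial limit of 25%, a crossed replicate block, runs with cluster 18 removed or counted as T-like, and tests of single clusters.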

Results

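Blood cells of pregnant rats were compared at gestational day 13.5 between 2 oil-treated controls and 2 samples exposed to TCDD at gestational day 6.5. The series concerns environmental stressors and the immune, trophoblast and endothelial cells around placentation, and these libraries cover circulating mononuclear cells. The libraries held 46691920 and 44021041 UMIs for oil replicates 1 and 2, and 42235819 and 48638173 for TCDD replicates 1 and 2. After filtering, 7335, 8302, 6539 and 7122 cells remained in that order, with medians of 3780, 3631, 4134 and 3846 UMIs per cell. Values given below for single libraries follow the same order. Hba-a1, Hba-a2, Hba-a3, Hbb and Hbb-b1 together took 0.411% and 0.012% of all UMIs in the oil libraries and 2.19% and 2.99% in the TCDD libraries. The beta-globin copy LOC100134871 was not counted there.

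The first comparison asked whether the make-up of the blood differed. T-like cells were 62.9% ± 13.7 (SD, n = 2) of kept cells in oil and 40.0% ± 26.7 (SD, n = 2) in TCDD, and monocyte-like cells were 14.0% ± 11.2 and 30.9% ± 25.9. B-like cells were 9.90% ± 1.26 in oil and 12.9% ± 0.178 in TCDD, and NK-like cells were 6.26% ± 7.36 and 11.4% ± 1.14. Erythroid-like cells were 0.491% and 0% in the oil libraries, the latter with an exact 95% upper limit of 0.0444%, and 1.10% and 2.22% in the TCDD libraries. Neutrophil-like cells were 0.535% ± 0.689 in oil and 1.70% ± 2.02 in TCDD, and plasma-like cells 0.374% ± 0.0849 and 0.402% ± 0.00677.

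Only B-like and erythroid-like cells among the named classes had higher shares in both TCDD libraries than in both oil libraries, with differences of 2.99 and 1.41 percentage points (exact permutation p = 0.333 each, the smallest possible). With the stricter cell filter the B-like shares were 1.27%, 2.34%, 5.68% and 1.87% and the groups overlapped. For T-like, NK-like, monocyte-like and neutrophil-like cells the groups overlapped (exact permutation p = 0.667 each), and for plasma-like cells p was 1 by the same exact test. Single libraries set the larger gaps. T-like cells were 53.3%, 72.6%, 58.9% and 21.2%, and monocyte-like cells 21.8%, 6.06%, 12.6% and 49.2%. Without TCDD replicate 2 the monocyte-like difference was -1.35 percentage points, the neutrophil-like difference -0.260 and the T-like difference -4.03. NK-like cells were 11.5%, 1.06%, 12.2% and 10.6%, and without oil replicate 2 their difference was -0.0849 percentage points. In oil replicate 2, cluster 18, which expressed Rag1, Dntt and Ptcra, held 6.41% of cells, against at most 0.0273% in any other library.

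**Figure D1:**
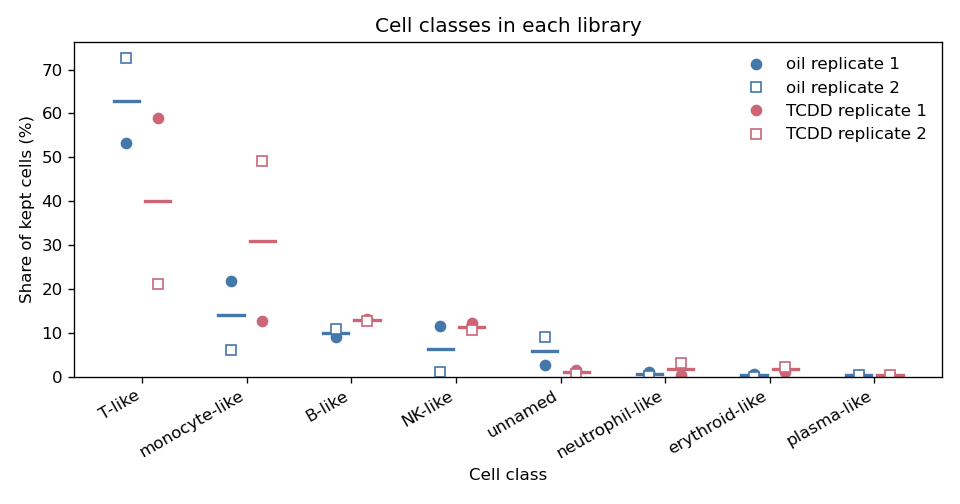
Share of kept cells (%, vertical axis) in each cell class (horizontal axis), with 1 point per library and a line at the mean of each group of 2. Monocyte-like cells reach 49.2% in TCDD replicate 2 and T-like cells 72.6% in oil replicate 2, while B-like shares lie at 9.01% and 10.8% in oil and at 13.01% and 12.8% in TCDD.

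Summed over all cells, the comparison asked which transcripts of the whole blood preparation differed. None of 11701 genes passed, and the smallest adjusted p was 0.931. The 5 higher genes with the smallest p were Hbe1, an embryonic beta-type globin, Rarres1, Ahrr, the AHR repressor and a direct target of the receptor, Folr2, a folate receptor of macrophages, and Trmt9b. Hbe1 counted 9, 0, 739 and 1844 UMIs, a ratio of totals of 306 (counting interval 161 to 670). Ahrr counted 0, 1, 33 and 18 UMIs, a ratio of 54.4 (9.34 to 2190). Rarres1 had a log2 fold change of 2.47 ± 0.39 (SE, n = 2 per group), Folr2 1.95 ± 0.36 and Trmt9b 4.13 ± 0.84. The 5 lower genes with the smallest p were Hat1, a histone acetyltransferase, at -1.13 ± 0.19, Rec114 at -2.91 ± 0.58, Sapcd2 at -0.997 ± 0.23, Thegl at -1.76 ± 0.40 and Cdca3, a cell division gene, at -1.13 ± 0.26.

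Several gene lists shifted in all cells with camera at the preset correlation. Of the cell cycle list, 20 of 22 members had negative estimates (adjusted p = 4.66e-08), such as Stmn1 at -0.78 and Mcm5 at -0.70 (adjusted p = 0.832 with an estimated correlation). Within T-like, NK-like and B-like cells 14 of 22, 18 of 22 and 10 of 17 members had positive estimates (camera adjusted p = 0.616, 0.382 and 0.978). Top2a was highest in NK-like cluster 14 and unnamed clusters 18 and 8 (1073.62, 542.16 and 218.46 CPM). Cluster 8 held 2.00%, 2.07%, 0.979% and 0.197% of kept cells, and cluster 14 2.14%, 0%, 1.82% and 1.43%. All 11 erythroid members had positive estimates (adjusted p = 7.30e-08), among them Bpgm at 1.30 and Fech at 1.62, and so had all 6 platelet members (adjusted p = 9.91e-06), such as Pf4 at 0.99 and Treml1 at 1.86 (each adjusted p = 0.832 with an estimated correlation). The platelet list had 3 members past the threshold adjusted over the list alone (Clec1b, Treml1 and Pf4), the AHR list 1 (Ahrr), and the other lists 0. Pf4 was highest, at 1438.81 CPM, in unnamed cluster 17, which is led by genes such as C1qa, C1qb and Folr2. That cluster held 0.0273%, 0.1325%, 0.245% and 0.253% of kept cells. Ppbp, Gp1bb and Gp5 were at most 0.45 CPM in every cluster, so the platelet list call does not show platelets as its source. The monocyte and macrophage (17 of 17 members positive), cytotoxic effector (15 of 15), B cell identity (14 of 16), MHC class II (8 of 8), NF-kB (16 of 18), immediate early (15 of 19), neutrophil granule (12 of 13) and NRF2 (11 of 13) lists shifted up, with adjusted p from 0.000201 to 0.0268 (each adjusted p = 0.832 with an estimated correlation). The ribosomal protein (71 of 77 members negative), naive and central memory T cell (10 of 11) and heat shock (11 of 12) lists shifted down, at adjusted p = 1.95e-05, 0.000684 and 0.00245. With an estimated correlation the adjusted p of these 3 was 0.863, 0.832 and 0.832. No member of any list passed over all genes. Only the cell cycle, erythroid and platelet calls held without any single library. Without oil replicate 2 the cytotoxic list passed in the opposite direction, down (adjusted p = 0.0176), and the neutrophil list turned down (0.943). Without TCDD replicate 2 the neutrophil (0.875) and NRF2 (0.413) lists turned down and the ribosomal list up (0.492). These shifts include the shares of cells given above. In 157 genes the unadjusted p was under 0.05, DESeq2 called 1 gene, and edgeR called 0 without any single library.

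In T-like cells, Art2b, which encodes an ADP-ribosyltransferase of the rat T cell surface (RT6), rose in the TCDD libraries. Its level was 133 and 127 CPM in oil and 292 and 321 CPM in TCDD, a log2 fold change of 1.24 ± 0.11 (SE, n = 2 per group, adjusted p = 0.00931). It was the only one of 10076 genes to pass. The further higher genes with the smallest p were Ccr9, a gut-homing chemokine receptor (1.45 ± 0.18, adjusted p = 0.0959), Gpr15, a homing receptor of the colon (2.32 ± 0.31, adjusted p = 0.0959), Ubd (1.80 ± 0.25) and Fam241a (0.76 ± 0.11). On the lower side were Hat1 (-1.05 ± 0.14, adjusted p = 0.0959), Nipsnap3b (-1.58 ± 0.24), Rec114 (-3.73 ± 0.64), Saraf, a brake on store-operated calcium entry (-0.70 ± 0.12), and Stom (-0.70 ± 0.13). The make-up of T-like cells differed between libraries. Cluster 0, led by Cd8a and Cd8b, held 33.0%, 28.4%, 43.1% and 49.2% of T-like cells, and cluster 2, led by Cd40lg and Cd28, held 27.5%, 54.2%, 25.01% and 14.3%.

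Genes of the AHR response were measured in T-like cells for 7 of 18 listed members. Ahrr counted 0, 1, 29 and 8 UMIs, a ratio of totals of 58.2 (counting interval 9.81 to 2360, edgeR adjusted p = 0.142). Nqo1, a quinone reductase induced through AHR and NRF2, had levels of 0.299, 0.294, 1.499 and 4.67 CPM and a log2 fold change of 3.24 ± 0.64 (adjusted p = 0.381). Tiparp, an AHR-induced ADP-ribosyltransferase, had 0.17 ± 0.29 and Ahr itself 0.38 ± 0.29. Ahrr and Nqo1 passed adjusted over the list alone, and the list shifted up with camera (adjusted p = 0.0426, and adjusted p = 0.832 with an estimated correlation). In all cells Nqo1 had levels of 9.07, 1.68, 12.1 and 37.1 CPM and a log2 fold change of 2.19 ± 1.01 (adjusted p = 0.931), Tiparp had 0.062 ± 0.22 and Ahr -0.19 ± 0.33. In the other classes Nqo1 had 2.62 ± 0.43 in NK-like cells (adjusted p = 1.00) and 0.90 ± 0.29 in monocyte-like cells (adjusted p = 1.00). Tiparp had -0.11 ± 0.18 in B-like, 0.29 ± 0.27 in NK-like and -0.11 ± 0.15 in monocyte-like cells, and Ahr -0.85 ± 0.38, -1.26 ± 0.50 and 0.066 ± 0.31, none past the threshold. All 5 AHR list members tested in B-like cells had negative estimates, such as Nfe2l2 at -0.47 (camera adjusted p = 0.0189, and adjusted p = 0.832 with an estimated correlation). Leaving out 1 library at a time lost the call of this list in 3 of 4 cases in T-like and in 2 of 4 in B-like cells. Cyp1a1 counted 0, 6, 0 and 0 UMIs over all cells and Cyp1b1 0, 7, 2 and 0, below the count minimum.

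Other lists in T-like cells shifted with camera. All 13 cytotoxic effectors had positive estimates (adjusted p = 6.82e-06), such as Ifng at 1.32 and Klrk1 at 0.37, and 20 of 27 interferon response members did (adjusted p = 0.000452), such as Stat1 at 0.34 and Bst2 at 0.40 (each adjusted p = 0.832 with an estimated correlation). All 7 MHC class II members had negative estimates (adjusted p = 2.50e-06), such as Cd74 at -0.71 and RT1-Da at -0.54, and so had 9 of 11 naive and central memory members (adjusted p = 0.00196), such as Sell at -0.48 (each adjusted p = 0.832 with an estimated correlation). Past the threshold adjusted over the list alone were 4 MHC class II genes (Cd74, RT1-Bb, RT1-Ba and RT1-Da) and 4 of the naive list (S1pr1, Ccr9, Sell and Ccr7, of which Ccr9 was higher), and 0 cytotoxic or interferon genes. The chemokine receptor and trafficking list did not shift (adjusted p = 0.189), with 6 genes passing adjusted over the list alone (S1pr1, Itgb7, Ccr9, Sell, Ccr7 and Itgb1). The erythroid list (6 of 8 positive, adjusted p = 0.000736) and the neutrophil list (3 of 3, adjusted p = 0.0273) also shifted up (each adjusted p = 0.832 with an estimated correlation). Hbb stood at 2.81, 0.126, 40.7 and 77.5 CPM and S100a9 at 2.09, 0.336, 2.998 and 10.98 CPM, transcripts of other blood cells. The MHC class II and erythroid calls held without any single library. Cd74, RT1-Ba, RT1-Bb and RT1-Da are, however, among the leading genes of B-like cluster 10, whose RNA may be carried over into T-like counts. Whether carried-over RNA enters the MHC class II call was not tested, and B-like shares were higher, not lower, in TCDD. Without oil replicate 2 the interferon list turned down (adjusted p = 0.614), and the cytotoxic (0.201), naive (0.0937) and neutrophil (0.257) calls were lost. Among T-like cells Gzmm, Nkg7 and Ccl5 were highest in cluster 1, with Gzmm at 1695.62 CPM against 3.75 to 73.37 in the other clusters, and this cluster held 7.5%, 2.0%, 7.4% and 17.6% of T-like cells. For T-like cells 581 genes had an unadjusted p under 0.05, DESeq2 called 21 genes, and leaving out oil replicate 1, oil replicate 2, TCDD replicate 1 or TCDD replicate 2 gave 159, 20, 9 and 0 genes. The Art2b call was lost without TCDD replicate 2 (log2 fold change 1.17, adjusted p = 0.0938) and with the replicate block (1.24, adjusted p = 0.193).

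In B-like cells, Nuak2, an AMPK-related kinase, and Sspn (sarcospan, a membrane protein of the dystrophin complex) fell and Hbb, an adult beta-globin, rose, out of 8445 genes. Nuak2 had 27.1 and 29.8 CPM in oil against 4.92 and 2.64 in TCDD, a log2 fold change of -2.88 ± 0.32 (SE, n = 2 per group, adjusted p = 0.00198). Sspn had 35.8 and 30.5 CPM against 11.6 and 8.59, at -1.70 ± 0.26 (adjusted p = 0.0265). Tested alone, cluster 10, with most B-like cells, had 6.40, 4.58, 4.75 and 1.83 CPM of Sspn (-0.57, adjusted p = 0.966), and cluster 11, with 1.47%, 1.08%, 2.31% and 4.65% of kept cells, had 149.8, 186.5, 38.8 and 17.5 CPM (-2.71, adjusted p = 0.00486). Hbb had 4.59 and 1.64 CPM against 53.9 and 99.7, at 4.70 ± 0.47 (adjusted p = 0.0265), with the globin load of the whole TCDD libraries also higher. In all kept cells Hbb made up 5.39% and 5.54% of beta-globin UMIs in the oil libraries and 44.98% and 45.2% in the TCDD libraries. Part of the Hbb rise may thus reflect how reads were counted among the copies. The next higher genes by p were Ptpn7 (0.92 ± 0.21), Ifit3 (2.00 ± 0.42), Fibp (0.77 ± 0.21) and Ms4a6e (1.52 ± 0.42), and the next lower were Ralgds (-1.10 ± 0.27), Mid2 (-1.38 ± 0.35) and Lmna (-0.84 ± 0.23), each at adjusted p = 0.952.

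Among the lists in B-like cells, 23 of 25 interferon response members had positive estimates (camera adjusted p = 3.07e-05), with Ifit3 at 2.00 the 1 gene passing adjusted over the list alone and Ifit2 at 0.82 (adjusted p = 0.832 with an estimated correlation). The erythroid list (6 of 7 positive, adjusted p = 2.12e-06, with Hbb passing over all genes and adjusted over the list alone) and the cytotoxic list (6 of 7, adjusted p = 0.0244) also shifted up (each adjusted p = 0.832 with an estimated correlation). Of the cytotoxic list, Gzmm stood at 10.1, 2.30, 8.98 and 14.9 CPM with overlapping groups, against 3236 to 4066 CPM in NK-like cells, whose share was also lowest in oil replicate 2. Lower as groups were heat shock (8 of 10 negative, adjusted p = 0.00304, Hspa5 at -0.49), NF-kB (10 of 13, adjusted p = 0.00921, Birc3 at -0.53), MHC class II (7 of 8, adjusted p = 0.0122, RT1-Da at -0.47), chemokine receptors and trafficking (10 of 11, adjusted p = 0.0122, Itgb1 at -0.56), naive and central memory (8 of 9, adjusted p = 0.0212, with Satb1 at -0.77 passing adjusted over the list alone) and ribosomal proteins (56 of 73, adjusted p = 0.00393). With an estimated correlation the adjusted p was 0.907 for ribosomal proteins and 0.832 for the 5 others of these. Only the erythroid call held without any single library. Without oil replicate 2 the interferon (adjusted p = 0.225) and cytotoxic (0.0602) lists turned down and the ribosomal list up (0.219), and without TCDD replicate 2 the naive list turned up (0.993). For B-like cells leaving out oil replicate 1, oil replicate 2, TCDD replicate 1 or TCDD replicate 2 gave 185, 12, 12 and 3 genes. The Sspn call was lost without either TCDD library (adjusted p = 0.0681 without replicate 1 and 0.352 without replicate 2), by DESeq2 (0.137), with library totals alone (0.107), with the replicate block (0.178) and with a mitochondrial limit of 25% (0.873), the Nuak2 call with the block (0.0538) and the Hbb call with the 25% limit (0.389).

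In NK-like cells, no gene of 8706 passed, and the highest rank went to Hbe1 with 1.82, 0, 201 and 504 CPM (log2 fold change 7.70 ± 0.72, SE, n = 2 per group, adjusted p = 0.0975). Hbb (3.83 ± 0.60), Nqo1 (2.62 ± 0.43), Cdhr1 (1.63 ± 0.30) and Mylpf (2.48 ± 0.56) followed among higher genes. The lower genes with the smallest p were Ramp1, a co-receptor for calcitonin gene-related peptide (-1.62 ± 0.36), the T cell receptor components Cd3e (-1.57 ± 0.41) and Cd3g (-1.72 ± 0.47), the chaperone Dnaja1 (-0.89 ± 0.24) and Osbpl3 (-0.80 ± 0.23). Oil replicate 2 held 88 NK-like cells, 83 of them in cluster 7, which is led by Xcl1 and Klrb1b and by Hbe1 itself. The other libraries held 753 to 841 NK-like cells, mostly in cluster 9, led by Gzma, Gzmb and Prf1. Cd3g stood at 69.7, 198, 41.4 and 30.6 CPM.

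Lists in NK-like cells that shifted were heat shock (9 of 10 negative, camera adjusted p = 3.16e-06, Hsph1 at -1.17), naive and central memory (7 of 9 negative, adjusted p = 0.0118, Sell at -1.40 and Lef1 at -1.39), immediate early genes (14 of 17 negative, adjusted p = 0.0225, Fosb at -0.69) and ribosomal proteins (58 of 72 negative, adjusted p = 0.0189). With an estimated correlation the adjusted p was 0.907 for ribosomal proteins and 0.832 for the other 3. Cytotoxic effectors were higher as a group (13 of 15 positive, adjusted p = 2.94e-05), such as Ccl5 at 0.39 and Gzmm at 0.28, and so was the erythroid list (6 of 6, adjusted p = 9.79e-06, each adjusted p = 0.832 with an estimated correlation). Adjusted over the list alone, Hbb and Hba-a1 passed in the erythroid list, and Nqo1 in the AHR list. Only the erythroid call held without any single library. Without oil replicate 2 the ribosomal list passed in the opposite direction, up (adjusted p = 4.05e-05), and the immediate early list turned up (0.986). For NK-like cells 92 genes had an unadjusted p under 0.05 and DESeq2 called 2. Leaving out oil replicate 1, oil replicate 2, TCDD replicate 1 or TCDD replicate 2 gave 404, 14, 3 and 1 genes with edgeR.

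In monocyte-like cells, 6 of 8802 genes passed. Cd300c2, a receptor of the CD300 family on myeloid cells, fell from 77.2 and 60.2 CPM in oil to 9.42 and 13.8 CPM in TCDD (log2 fold change -2.51 ± 0.22, SE, n = 2 per group, adjusted p = 0.000997), and Cxcl1, a neutrophil-attracting chemokine, fell from 39.3 and 41.9 to 15.4 and 11.9 CPM (-1.61 ± 0.20, adjusted p = 0.0178). Lpl, lipoprotein lipase, rose from 6.65 and 3.06 to 26.4 and 25.4 CPM (2.22 ± 0.29, adjusted p = 0.0200), and Cst7, the protease inhibitor cystatin F, rose from 72.2 and 65.3 to 125 and 158 CPM (1.04 ± 0.15, adjusted p = 0.0460). The largest change was in RGD1562667, which has no gene symbol, from 288 and 263 to 1.88 and 2.27 CPM (-6.97, adjusted p = 5.65e-09), and AABR07003235.1 also fell (-2.94, adjusted p = 0.0403). The next genes by p were Ccn5, with 0.151, 0, 3.45 and 4.33 CPM, Mcemp1 (0.88 ± 0.16) and Cadm3 (1.56 ± 0.34) on the higher side, and Hat1 (-1.12 ± 0.20), Cadm1 (-1.41 ± 0.27) and Ccnd1 (-1.36 ± 0.27) on the lower.

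Of the interferon response list, 27 of 28 members had negative estimates in monocyte-like cells (camera adjusted p = 1.57e-08), such as Cmpk2 at -1.14 and Ifih1 at -0.58 (adjusted p = 0.832 with an estimated correlation). All 11 heat shock members did (adjusted p = 1.68e-05), such as Hsp90ab1 at -0.47, and so did 15 of 18 NF-kB members (adjusted p = 0.0128), such as Icam1 at -0.34 (each adjusted p = 0.832 with an estimated correlation). Among 10 cytotoxic effectors 9 had negative estimates (adjusted p = 3.86e-05, adjusted p = 0.832 with an estimated correlation). Adjusted over the list alone 5 of these passed, Nkg7, Gzmk, Gzmm and Ccl5 on the lower side and Cst7 on the higher, while the interferon, heat shock and NF-kB lists had 0. Of the transcripts of other blood cells in the same cells, Cd3g stood at 33.4, 40.8, 20.1 and 10.1 CPM and Hbb at 2.42, 0, 48.97 and 107 CPM. Higher as groups were the erythroid (6 of 7 positive, adjusted p = 8.93e-06), ribosomal (53 of 73, adjusted p = 0.00855) and mitochondrially encoded lists (12 of 13, adjusted p = 0.0212, ND3 at 0.38). With an estimated correlation the adjusted p was 0.900 for ribosomal proteins and 0.832 for the other 2. Only the erythroid call held without any single library. Without oil replicate 1 the interferon (adjusted p = 0.280) and heat shock (0.944) lists turned up. Without TCDD replicate 2 the NF-kB list turned up (0.145) and the ribosomal (0.177) and mitochondrial (0.993) lists down. For monocyte-like cells leaving out oil replicate 1, oil replicate 2, TCDD replicate 1 or TCDD replicate 2 gave 12, 17, 22 and 3 genes. The Lpl, Cxcl1 and Cst7 calls were lost without TCDD replicate 2 (adjusted p = 0.232, 0.277 and 0.457) and that of Cst7 also without oil replicate 1 (0.0856). The AABR07003235.1 call was lost without oil replicate 1 or TCDD replicate 2, and Lpl had a log2 fold change of 0.65 (adjusted p = 0.970) with the stricter cell filter. Those of RGD1562667 and Cd300c2 held in every setting run on the class. No such setting can tell TCDD apart from a genotype difference between the groups, and the labels give no strain or litter.

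**Figure D2:**
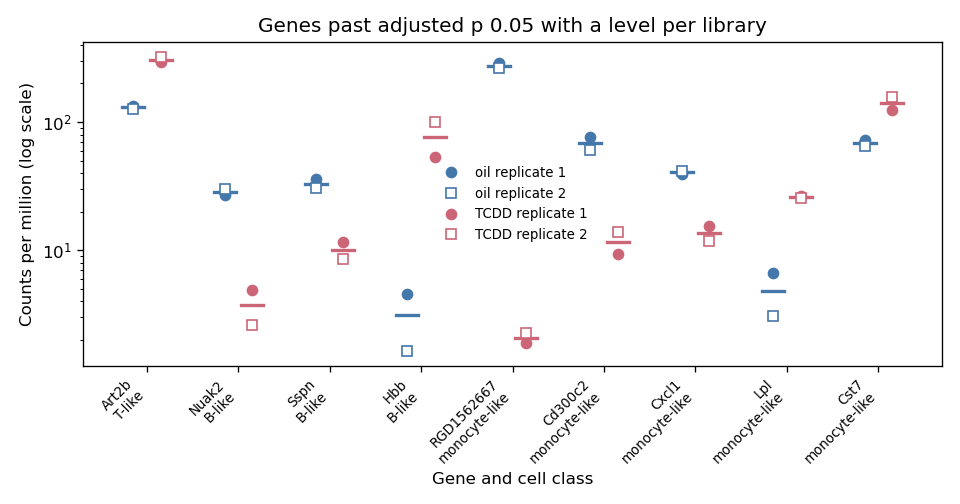
Level in CPM (vertical axis, log scale) of genes past adjusted p 0.05 in T-like, B-like and monocyte-like cells (horizontal axis), with 1 point per library and a line at the mean of each group of 2. AABR07003235.1, which also passed in monocyte-like cells, is not drawn. Art2b lies at 133 and 127 in oil and at 292 and 321 in TCDD, and RGD1562667 at 288 and 263 in oil and at 1.88 and 2.27 in TCDD.

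Whether the TCDD difference itself varied between classes was tested by interaction. Of 10779 genes, 8 differed between monocyte-like and T-like cells. Cd7, a T and NK cell surface protein, had a log2 fold change of 1.23 in T-like and -1.49 in monocyte-like cells (interaction -2.79 ± 0.29, adjusted p = 0.00371), and Sqor, a mitochondrial sulfide-oxidising enzyme, had 2.18 and 0.03 (interaction -2.11 ± 0.29, adjusted p = 0.0264). Cd7 was among the leading genes of T-like cluster 1 and NK-like cluster 7. Its change in monocyte-like cells may therefore be that of carried-over RNA, which was not tested. No gene of 9609 differed between B-like and T-like cells and none of 9722 between NK-like and T-like cells with edgeR, with 465 and 159 at an unadjusted p under 0.05. Leaving out oil replicate 1, oil replicate 2, TCDD replicate 1 or TCDD replicate 2 gave 129, 57, 75 and 12 genes for monocyte-like against T-like cells, 161, 1, 68 and 1 for B-like and 153, 3, 1 and 0 for NK-like against T-like cells. In plasma-like cells no gene of 1775 passed, 71 had an unadjusted p under 0.05 and DESeq2 called 0. In the lists for T cell activation and checkpoint, MHC class I processing, cholesterol biosynthesis, p53 targets, glucocorticoid response, and endothelial and trophoblast genes no comparison passed, with smallest adjusted p of 0.0583, 0.0762, 0.0541, 0.211, 0.378 and 0.797, and Msmo1 in B-like cells passed adjusted over the cholesterol list alone.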

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

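The tests of barcodes with at least 2 of 3 genes, of thymus cells added, of a mislabelled sample, of Hbe1 in NK-like cells, of the cluster make-up, of the genotype and of the other splits were chosen after the results they bear on had been seen.

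The TCDD difference was not the same in monocyte-like and T-like cells for 8 genes, by a test of the interaction. The effect was lower in monocyte-like cells, on the log2 scale, for Cd7 (-2.79), AC142181.1 (-2.12), Sqor (-2.11), S100a9 (-1.94), the T cell genes Cd27 (-1.69) and Lck (-1.36) and the chemokine Ccl4 (-1.49). It was higher for S100a4 (1.03), with a log2 fold change of 0.27 in monocyte-like and -0.71 in T-like cells. Without oil replicate 1 the calls of S100a9 (adjusted p = 0.9499), Cd27 (0.651), Lck (0.0778) and S100a4 (0.0705) were lost. Without oil replicate 2 the call of S100a4 was lost (0.0933), as it was with RLE factors (0.0648), and without TCDD replicate 2 those of AC142181.1 (0.724), Cd27 (1.00), Lck (1.00) and Ccl4 (0.0774). Cd7, Lck and Cd27 in monocyte-like cells and S100a9 in T-like cells are transcripts of other cell types. AC142181.1 was among the leading genes of T-like cluster 3. Carried-over RNA may therefore enter these interactions, which was not tested.

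Barcodes left out by the filters carried more globin in the TCDD libraries, counted over Hbb, the alpha globins and Hbe1. These genes took 4.58% and 3.49% of UMIs in TCDD replicates 1 and 2 against 0.289% and 0.0376% in oil replicates 1 and 2. The kept cells held 0.883% and 2.25% against 0.343% and 0.00104%. Hbb-b1 and LOC100134871 were not counted. In kept cells of oil replicate 1 they held 29227 and 74129 UMIs and Hbb 5893. In TCDD replicate 1 they held 30273 and 74112 and Hbb 85343. The gap thus also depends on how reads were counted among the copies.

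Globin transcripts were higher in B-like and NK-like cells of the TCDD libraries, and free RNA from erythroid cells may account for part of this. In B-like cells Hba-a2 per Hbb was 0.867 times its ratio in erythroid-like cells in the lower TCDD library, as 1 common source requires. The tables argue against that source for Hbe1, whose ratio to Hbb in NK-like cells was 92920 and 376300 times that in erythroid-like cells in the TCDD libraries. Hbb made up 5.39% and 5.54% of beta-globin UMIs in the oil libraries and 44.98% and 45.2% in the TCDD libraries, while beta per alpha globin in the lower TCDD library was 1.015 times that of oil replicate 1, so part of the Hbb difference may reflect reads of the oil libraries counted to other beta-globin copies. A difference in beta-globin genotype between the groups and an effect of TCDD on Hbe1 both stay open.

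Oil replicate 2 stood apart, with a cluster of immature T cell character (532 cells, against 4 in the other libraries together) and few NK-like cells. Thymus cells added to otherwise like blood are argued against, because NK-like cells were 8.94% of NK-like plus B-like cells there (exact 95% interval 7.23 to 10.9) and 45.3% to 56.0% in the other libraries. The cell filters were weighed by the share of all barcodes with a Rag1, Dntt or Ptcra UMI, 2.96 times that of the next library, which decided nothing. A test chosen after that result, on barcodes with at least 2 of the 3 genes, gave 105 times the next library. It argues against the filters as the source of the cluster, although Ptcra is also known in plasmacytoid dendritic cells. The 3 genes lead that cluster, so this test does not bear on the few NK-like cells. A mislabelled or mixed sample could also give the 4 cells elsewhere, and with 1 such library it cannot be told apart from a biological difference, for which no test was run.

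Art2b was higher in T-like cells of both TCDD libraries. A different cluster make-up of these cells is argued against, since Art2b passed in each of the 4 clusters 0 to 3 tested alone, although it helps to define cluster 0 and in cluster 2 was lost without either TCDD library (adjusted p = 0.293 and 0.527). Fewer recently emigrated T cells, marked by Thy1, could not be judged from 11 Thy1 UMIs in all. The animals' genotype, since RT6 alleles are known to differ between rat strains, could give the log2 difference of 1.24. It cannot be told apart from TCDD, because the labels give no strain or litter and gene counts hold no alleles. An effect of TCDD stays open as well.

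Splits of the 4 samples other than the real one called up to 3 genes in T-like cells (real 1), 4 in B-like (real 3), 1 in NK-like (real 0) and 7 in monocyte-like cells (real 6). Splits with as many calls, the real one included, numbered 2, 2, 3 and 2 of 3, and 3 splits are too few for a share under 0.05. For NK-like cells the 3 of 3 was fixed in advance, because the real split called 0 genes.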

How the results depend on the processing

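The mitochondrial limit of 25%, the crossed block and the runs on cluster 18 were chosen after the data were seen, and all other settings before. The cause of each change below was not tested. The main counts are 0 genes in all cells, 1 in T-like, 3 in B-like, 0 in NK-like and 6 in monocyte-like cells. DESeq2 called 1, 21 and 2 genes in all, T-like and NK-like cells. Without the low-count filter the counts were 157 in T-like, 22 in B-like, 7 in NK-like and 64 in monocyte-like cells, and 48, 69 and 3 for the interactions of B-like, monocyte-like and NK-like with T-like cells. The stricter cell filter gave 6 genes in T-like cells. Leiden resolution 0.5 gave 3 in monocyte-like cells, and a mitochondrial limit of 25% gave 1 in B-like and 3 in monocyte-like cells. Counting cluster 18 as T-like gave 0 genes (Art2b adjusted p = 0.0575). The gene list calls went from 44 to 0 with an estimated correlation, and the directional test of fry called 0. With the fry test for changes in either direction the AHR list passed in T-like cells (adjusted p = 0.00977). Of these 44 calls, 8 held without any single library, 16 turned direction without at least 1 library and 2 of these were then called in the opposite direction.

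The labels share the numbers 1 and 2 but do not tie them to a batch. With them as a replicate block, 0 genes were called in all and T-like, 2 in B-like, 3 in NK-like and 35 in monocyte-like cells, and 43 list tests. Same-numbered samples deviated with correlations of -0.544, -0.277, -0.091, -0.0363 and -0.119 in these classes. The crossed pairing called 0, 88, 27, 1 and 3.

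Leaving out single libraries gave 0 to 159 genes in T-like, 3 to 185 in B-like, 1 to 404 in NK-like and 3 to 22 in monocyte-like cells, and 1 to 161, 12 to 129 and 0 to 153 for the same interactions. The remaining library of a group is then assumed to vary like the other group. Such fits can call more genes than the full test, so a call that held in them is weak support. Share differences ranged from -41.7 to -4.03 points for T-like, 2.10 to 3.88 for B-like, -0.0849 to 10.3 for NK-like, -1.35 to 35.3 for monocyte-like, -0.260 to 2.60 for neutrophil-like, 0.856 to 1.97 for erythroid-like and -0.0312 to 0.0888 for plasma-like cells. Plasma-like cells reversed with the stricter filter (-1.89) and at 25% (-0.0515). Shares of single libraries also moved. T-like cells were 10.6%, 39.0%, 26.8% and 4.87% with the stricter filter. Monocyte-like cells were 12.3%, 4.63%, 6.61% and 43.7% at Leiden resolution 2.0.

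Single genes reversed as log2 fold changes, none of them past the threshold. Leaving out single libraries moved Tiparp from -0.15 to 0.29, Ahr from -0.56 to 0.28, Slc7a11 from -4.44 to 0.43 and Fn1 from -0.13 to 2.53 in all cells, and Tiparp from -0.21 to 0.70 in T-like and from -0.32 to 0.14 in B-like cells. In NK-like cells Tiparp moved from -0.052 to 0.57, Ahr from -1.67 to 1.18 and Hsph1 from -1.56 to 0.70, and in monocyte-like cells Tiparp from -0.27 to 0.056 and Ahr from -0.24 to 0.83. With the stricter filter Tiparp was -0.19 and Sell 0.094 in all cells and Ccnd1 0.21 in monocyte-like cells. In named classes only, Slc7a11 was 0.0081, Bpgm -0.021 and Fech -0.017, and without cluster 18 Slc7a11 was 0.0012.

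Cst7 lost its call under 8 settings (adjusted p from 0.0665 to 0.457), Lpl under 4 (0.0631 to 0.970) and Cxcl1 under 4 (0.0969 to 1.00). AABR07003235.1 lost its call under 7 (0.0593 to 0.480) and, like Cxcl1, could not be tested with the stricter filter. Of all values of the named genes that kept direction, 1941 kept their side of the threshold, 137 passed it and 37 no longer did, the losses of Cst7, Lpl and Cxcl1 included. The stricter filter used the main labels and left B-like and NK-like cells under 20 in some samples, so those tests were not run, nor was the neutrophil-like comparison. Of the classes tested for genes, plasma-like cells were the shallowest, with 23 to 36 cells and at least 0.0429 M UMIs per library, and NK-like cells came next, with 88 cells in oil replicate 2. In all cells the spread between libraries limits the test.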

Other observations

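Tests of single clusters were chosen after the results for the classes were seen, each with its own adjustment and none across clusters, in the 11 clusters with at least 20 cells per sample. In the CD8-led cluster 0, 16 genes passed of 8853, 10 higher and 6 lower in TCDD. The interferon-inducible membrane protein Ifitm1 rose by 1.10 (511.7 and 433.3 to 862.3 and 1160.0 CPM, adjusted p = 0.0153), and it also rose by 1.08 in cluster 1, whose cells express Ly49 receptors. Sqor rose by 1.91, Hic1, a transcriptional repressor, by 3.12, Jaml, an adhesion molecule, by 1.42, Ccr9 by 0.98 and Lag3, an inhibitory receptor, by 0.78. Sell, the lymph node homing receptor L-selectin, fell by 0.74 (adjusted p = 0.0153), the transcription factor Myb by 1.17 and Lysmd2 by 1.68. These calls stayed without any single library. Such fits leave 1 sample in a group and can call more genes than the full test, so this is weak support. The same holds for the calls of other clusters below. The 2 other splits of the samples called 1 and 3 genes in this cluster, against 16 in the real one. Without single libraries the counts ran from 49 to 247.

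In the Cd40lg-led clusters 2 and 3, Saraf fell by 0.99 and 0.96. The Saraf calls were lost without TCDD replicate 1 (adjusted p = 0.536 and 0.173), and that of cluster 2 also without TCDD replicate 2 (0.117). Cluster 6 was led by Ramp3, Rora and Icos, with Foxp3 and Gata3 further down its leading genes. There the AHR target Nqo1 rose by 3.04 (2.74 and 3.39 to 16.0 and 41.8 CPM, adjusted p = 0.0298), a call lost without TCDD replicate 2. Gpr15 also leads this cluster, so its level there is not given as a result. In cluster 11 of the B-like cells Sspn fell by 2.71 and the integrin Itgb1 by 1.74, and both held without any single library, while Sspn was not called in cluster 10 (-0.57, adjusted p = 0.966). The other splits called up to 3 genes in cluster 2 (real 4), 4 in cluster 3 (real 3), 9 in cluster 6 (real 7) and 0 in cluster 11 (real 3). In plasma-like cells leaving out TCDD replicate 1 gave 435 genes and the full test 0.

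In cluster 7 of the NK-like cells 3 of 5069 genes passed. Art2b rose by 1.76 (94.5 and 66.8 to 324.3 and 247.9 CPM, adjusted p = 0.000638) and held without any single library, and Hbb rose by 3.42, a call lost without oil replicate 2 (0.0713) or TCDD replicate 2 (0.142). The third, Hbe1, leads this cluster, so its level there is not given as a result. The other splits called 1 and 0 genes.

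RGD1562667 was lower in both monocyte-like clusters, 4 and 5 (-6.89 and -6.98), where the other splits called up to 9 genes (real 3) and 6 (real 1). Cd300c2 passed in cluster 4 (-2.50, adjusted p = 0.000352) and not in cluster 5 (-2.35, adjusted p = 0.826). Cst7 passed in cluster 4 alone (1.23, adjusted p = 0.0376), and Lpl, Cxcl1 and AABR07003235.1 in neither. In cluster 7 of the NK-like cells RGD1562667 stood at 23.2 and 12.7 CPM in oil and at 21.9 and 23.9 CPM in TCDD. The difference between these cell types was not tested. Of 7438 genes tested in T-like, B-like, NK-like and monocyte-like cells, 74 moved 1 way in all 4 classes with groups that did not overlap, and the other splits of the samples gave 48 and 174 such genes.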
